A study of Mus musculus with 12 samples.

How the data were processed

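RNA of mouse hearts was measured by total RNA sequencing in 12 libraries, 3 each of PTCD1 knockout (KO) and wild-type (WT) hearts, untreated or treated with CMC. Per the labels' protocols, cytoplasmic ribosomal RNA was depleted with Ribo-Zero and libraries were made with TruSeq chemistry. Per the submitters' processing notes, HISAT2 2.0.5, SAMtools 1.5, featureCounts 1.5.1 and DESeq2 1.16.1 were used with the mm10 genome; the role of each is not spelled out there. The strandedness of counting, the mice per library and any sequencing batch are not given in the sources used here.

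The deposited gene tables hold raw read counts per gene, with the columns that featureCounts writes, separately for untreated and CMC libraries. A table deposited by the authors gives a log2 fold change, its standard error, a p-value and an adjusted p-value for each gene, without naming its tool. In the deposited gene ontology tables the authors give p-values for each category and the numbers of genes per category, and other numbers of those genes that were called. The p-values of these tables are not adjusted as far as the deposited file says, and their background is not stated. The deposited per-base tables of the mitochondrial genome, made with pysamstats per the file headers, hold counts of reads, matches, mismatches, deletions and insertions. No deposited value exceeds a depth of 1000000, and 237 positions of mt-Rnr1 and mt-Rnr2 reach at least 900000 in some library, so the depth of these positions may be limited; 1797 positions lie within 151 bases of them.

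Gene names, types and positions came from GENCODE M21 on mm10. Of 51911 features, 51632 had a symbol and 279 had none, and 36 were mitochondrial. Total depth was 10389398 to 12462093 counts per library, and 2683284 to 3187748 nuclear counts limit the precision for nuclear genes: a gene at 0 counts over the 3 libraries of a group was given a floor of 3 counts over the group. Genes with 1 to 3 counts over a group are given as ratios with 95% counting intervals. Genes that share reads with paralogs or pseudogenes, overlap another gene, or have an antisense partner are uncertain.

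Each comparison of 2 groups used the 6 libraries of those groups. Genes were filtered with filterByExpr, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood test with Benjamini-Hochberg adjustment, called at 0.05. The difference of the CMC effect between genotypes was a contrast in a fit of all 12 libraries. In all, 5 comparisons were made: KO against WT in untreated and in CMC libraries, CMC against untreated in WT and in KO, and the difference of these CMC effects. Each gene list with at least 3 tested members was tested with camera of limma 3.58.1, with a preset correlation of 0.01. The test used log2 counts per 1000000 with a prior count of 2, and p was adjusted by Benjamini-Hochberg over the lists. Lists overlap, since several genes belong to more than 1. There were 49 lists, of which 43 could be tested.

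Depth over 37 mitochondrial genes and the control region was taken as log2 mean depth scaled by the TMM effective nuclear library size and tested with limma. Depth across 10 bases at each junction of neighbouring genes was divided by the geometric mean of the depth of both genes. Positions were tested with limma on the log2 odds of mismatches and deletions, with 0.5 added, where every library had a depth of at least 100 and the mean share was at least 1%. Steps were the log2 ratio of the depth at the next 3' base to that at the base on the coding strand, with 1 added. Deletions alone were tested with edgeR with depth as an offset, where deletions summed to at least 20; this test, and a minimum share of 0.1% for variants, were chosen after the data were seen. The other tests of the comparisons, the groups, the gene lists and the rule for named genes were fixed before the data were examined, while tests of explanations, with 1 exception named there, were chosen after the result was seen. Analysis used R 4.3.3, version 1.17.8 of data.table and DESeq2 1.42.0 for an alternative test.

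The rule for named genes took Ptcd1 and the other 16S factors, and for KO against WT the 10 largest positive and 10 largest negative log2 fold changes among called protein-coding genes with a mean of at least 1 count per 1000000, a symbol that is not a predicted gene and no overlap between groups. From each list it took up to 4 called members with the largest changes, or up to 2 abundant ones where fewer than 4 were called. For CMC comparisons and the difference of effects it took 5 genes each way, for the mitochondrial genome mt-Rnr1, mt-Rnr2 and the 4 largest changes each way, and for positions and steps the 5 smallest p values and up to 10 called positions of mt-Rnr2. Position 2509, the position of mt-Rnr2 with the smallest p for deletions between KO and WT after CMC, the other deletion sites, and 4658, 8861 and 2656 were chosen after their values were seen, as were mt-Nd6, the other mitochondrial mRNAs and the gene ontology categories.

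Code was tested on simulated data, which for genes were drawn from the real means and depths, with 50 genes changed at each size. For untreated KO against WT, 46% of genes changed 1.25-fold were called, 74% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 4 false calls among 12228 genes. After CMC these were 22%, 72%, 92% and 100%, with 8 false calls of 12144. For CMC in WT they were 20%, 70%, 96% and 100%, with 7 false calls of 12098, and for CMC in KO 30%, 70%, 94% and 100%, with 7 of 11911. For the difference of effects they were 18%, 52%, 88% and 100%, with 6 of 12788. In the real untreated KO against WT comparison far more genes were called, 7079 of 12228. The adjustment of p depends on that share, so these percentages need not hold there. Simulated lists were called in 5 of 5 cases, with 1 false call among the rest of the 40 lists. Their genes were drawn independently of each other with a fixed spread. They thus do not show how often real lists, whose genes can be correlated, would be called falsely. Of 50 simulated steps of 0.2 log2 units 46 were called, with 2 false calls of 14780. Real steps called with CMC were smaller, with median changes of 0.0123 in WT and 0.00818 in KO. Of 50 deletion sites lowered by 2 log2 units 33 were called, with 1 false call of 2486. These were chosen among sites with more deletions than the test required. Simulated positions, with log2 odds changed by 1.58, were called in 50 of 50 cases, with 2 false calls of 1000. Simulated shifts of gene depth by 0.5 log2 units were called in 5 of 5. Depths and spreads of both were made up, so they do not show how often real changes would be called.

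The alternatives were size factors of DESeq2, no filter on low counts, at least 10 counts in every library, the DESeq2 Wald test, all 12 libraries in 1 fit, an adjusted p under 0.01, at least 2-fold change, mitochondrial genes left out, the replicate number as a block and each library left out in turn. For lists an estimated correlation and fry were tried. For mitochondrial depth they were median depth, the share of mitochondrial depth, gene counts in place of depth, junction windows of 4 and 20 bases and CMC libraries in place of untreated libraries. For positions and steps they were depth minimums of 20 and 1000, mismatches only, a quasi-binomial model and the mean of 3 bases on each side. Leaving out genes of the X and Y chromosomes, leaving out positions near the depth limit, a minimum share of 0.1% for variants, deletions alone, and deletions after CMC with each library scaled by the median of its rates at the other positions with more deletions after CMC in both genotypes were added after the data were seen. Other splits of the samples were counted for each test across genes or positions, 10 for each comparison of 3 against 3 libraries and 40 for the difference of effects.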

Results

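Total RNA from hearts of Ptcd1 knockout mice and of wild-type mice was sequenced after removal of cytoplasmic ribosomal RNA, with and without CMC, a carbodiimide that binds pseudouridine and can stop or disturb reverse transcription there. PTCD1 is a mitochondrial protein of the pentatricopeptide repeat family. The comparisons ask what its knockout does to RNA levels in the heart, and to the 16S ribosomal RNA of the large mitochondrial ribosomal subunit, which mt-Rnr2 encodes. The 12 libraries form 4 groups of 3: knockout (KO) and wild type (WT), each untreated or after CMC. Total counts ran from 10389398 to 12462093 per library, and counts in nuclear genes from 2683284 to 3187748, and 18136 to 18932 genes were detected. Mitochondrial transcripts took 73.0% ± 0.244 (SD, n = 3) of counts in KO and 72.5% ± 0.395 in WT untreated libraries, and 75.2% ± 0.380 and 71.2% ± 1.04 after CMC. The labels do not say whether the replicates are separate animals, so each p measures the spread between these samples. In untreated libraries that spread was only somewhat above counting error. Over nuclear genes the chi-square of replicate counts was 1.12 to 1.21 per degree of freedom in KO and 1.12 to 1.13 in WT. The biological coefficient of variation of untreated KO against WT was 2.43%. The p-values and counts of calls may thus not cover the spread between animals. Fold changes below are KO over WT unless stated otherwise.

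Ptcd1 (ENSMUSG00000029624.10, mm10 chromosome 5, 145147514 to 145167108, minus strand) was low but present in every KO library. Its counts were 28, 17 and 19 in the untreated KO libraries and 78, 71 and 74 in the untreated WT libraries. After CMC they were 23, 21 and 20 in KO and 79, 103 and 74 in WT. Per 1000000 nuclear counts, Ptcd1 stood at 6.99 ± 1.78 (SD, n = 3) in KO and 24.8 ± 0.980 in WT untreated hearts. With TMM scaling over all genes, on which the edgeR fold changes of genes below rest, it fell 3.82-fold (log2 fold change -1.93, SE 0.19, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.08e-19). All 6 KO libraries lay below all 6 WT libraries.

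KO hearts held less 16S rRNA, while most other transcripts of the mitochondrial genome rose. In untreated libraries mt-Rnr2 fell 7.58-fold (log2 fold change -2.92, SE 0.02, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.78e-237). As a share of mitochondrial counts, which is another scale, it took 65.1% ± 0.302 (SD) in WT and 9.06% ± 0.149 in KO. The 12S rRNA of the small subunit, mt-Rnr1, moved the other way and rose 3.80-fold (log2 1.93, SE 0.02, edgeR adjusted p = 2.24e-194), and its share of mitochondrial counts was 6.15% ± 0.0789 in WT and 24.7% ± 0.124 in KO. Of the 11 mitochondrial mRNA features, which hold 13 genes since overlapping pairs were counted together, 10 rose and 1 fell, with the same counts when adjusted over the list alone. The largest rises among them had log2 fold changes of 2.03 for mt-Nd1, 2.00 for mt-Nd2 and 1.78 for mt-Nd3. Smaller rises were seen for the joint mt-Atp8 and mt-Atp6 feature (1.43), the mt-Nd4l and mt-Nd4 feature (1.18), mt-Co2 (1.13), mt-Cytb (0.94), mt-Co3 (0.89) and mt-Co1 (0.66). The list was higher by camera (adjusted p = 9.98e-05), a call that was lost with an estimated correlation (adjusted p = 0.279 with an estimated correlation). At mt-Nd5 the log2 fold change was 0.10, and its call was lost with all 12 libraries in 1 edgeR fit (Benjamini-Hochberg adjusted p = 0.184). The mRNA that fell was mt-Nd6 (-1.35), which lies on the other strand and overlaps mt-Nd5; whether counting used strand is not given in the sources used here, so its value is uncertain. Both rRNAs moved, 1 up and 1 down. Both tRNA genes with enough counts to be tested rose, mt-Tl1 (2.78, SE 0.54) and mt-Tm (1.72, SE 0.31). Counts were the same when adjusted over each list alone, and neither list had the 3 members that camera needed. Reads of 151 bases are longer than these tRNA genes, of 75 and 69 bases, so they may stem from longer transcripts.

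**Figure D1:**
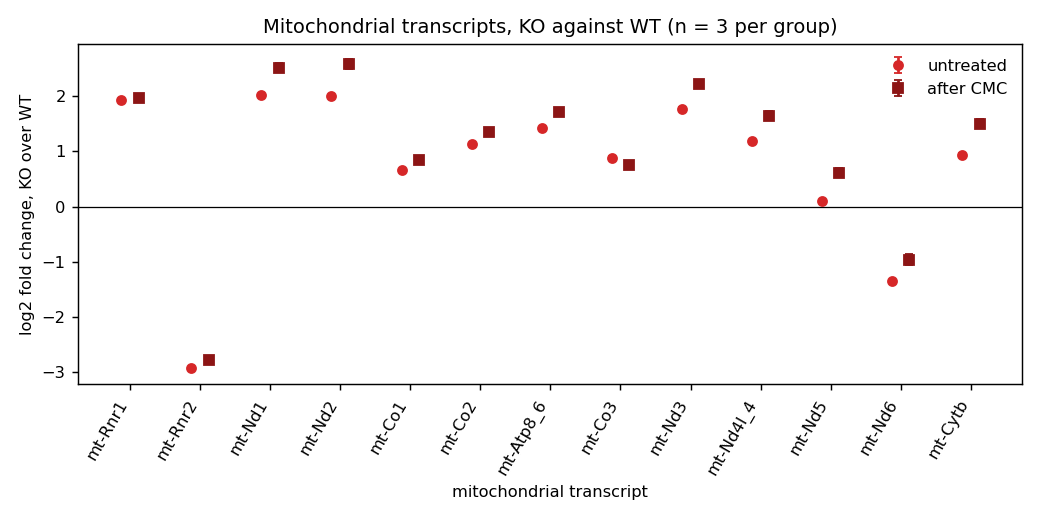
Log2 fold change of mitochondrial transcripts in KO against WT hearts (points, with standard errors that are mostly smaller than the symbols), for untreated libraries (circles) and libraries after CMC (squares), n = 3 per group. mt-Rnr2 lies at -2.92 and -2.78, while mt-Rnr1 lies at 1.93 and 1.96 and mt-Nd1 at 2.03 and 2.52.

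Read depth across the junctions of neighbouring mitochondrial genes was also compared. It counts reads that end near a junction as well as reads that cross it. The junction between the 16S gene and mt-Tl1, the tRNA gene just downstream, had more relative depth in KO. Depth across it was 0.306 of the geometric mean of its flanking genes in KO and 0.0450 in WT (log2 2.77, SE 0.03, limma, Benjamini-Hochberg adjusted p = 7.37e-09). At the upstream end of 16S, between mt-Tv and mt-Rnr2, the share was also higher in KO, 0.149 against 0.0553 (log2 1.43, limma adjusted p = 3.99e-06). The mt-Tt and mt-Tp junction rose too (log2 1.53), and that between mt-Tf and mt-Rnr1 rose less (0.37). Other junctions had less depth relative to their genes, led by mt-Atp6 and mt-Co3 (0.0901 in KO and 0.381 in WT, log2 -2.08), then mt-Co2 and mt-Tk (-0.95), mt-Nd4 and mt-Th (-0.90) and mt-Te and mt-Cytb (-0.90). Of 36 junctions, 24 differed, 9 higher and 15 lower in KO. The mt-Rnr1 and mt-Tv junction (log2 -0.44, limma adjusted p = 0.128) did not pass, but passed without WT_untreated replicate 2 (limma adjusted p = 0.00535) and in the CMC libraries in place of untreated ones (log2 -1.05, limma adjusted p = 0.000869). These ratios share their denominators with the change in the genes themselves, and depth over mt-Rnr2 in WT met a limit in the deposited tables. Depth counts both strands, and mt-Tt and mt-Tp, like mt-Te and mt-Cytb, lie on opposite strands.

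Mean depth per gene also covered tRNAs with too few counts for the test of genes. Of 38 mitochondrial features, 37 differed between KO and WT untreated libraries, 30 higher and 7 lower (limma, Benjamini-Hochberg). Depth fell by 2.77 log2 units over mt-Rnr2 and rose over mt-Tf (2.53), mt-Tl1 (2.44), mt-Nd1 (2.02) and mt-Nd2 (1.98). The other falls included the tRNA genes mt-Th (-0.78), mt-Ts2 (-0.75), mt-Td (-0.72) and mt-Te (-0.51). mt-Tk did not pass (0.28, limma adjusted p = 0.127). After CMC 32 of 38 differed, 29 higher and 3 lower: mt-Rnr2, mt-Th (-0.80) and mt-Ts2 (-0.66) were lower again, while the other falls did not pass, with mt-Td at 0.10 (limma adjusted p = 0.585), mt-Te at -0.18 (0.212), mt-Nd6 at 0.21 (0.204) and mt-Tl2 at -0.04 (0.903). Depth counts reads of both strands, so overlapping transcripts add up. Reads of 151 bases are longer than the longest tRNA gene, mt-Tl1 (75 bases), so depth over tRNA genes need not measure the tRNA itself.

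Around mitochondrial RNA, the nuclear genes for 16S maturation itself changed little, and those of the mitoribosome went both ways. Apart from Ptcd1, 7 genes known to act with 16S rRNA were measured. Ngrn alone passed in untreated libraries (log2 0.37, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0363); its call was lost with DESeq2 (adjusted p = 0.183), with all 12 libraries in 1 edgeR fit (0.0523), without KO_untreated replicate 1 (0.242) and without WT_untreated replicate 2 (0.312). The values of the others were 0.44 for Fastkd5 (edgeR adjusted p = 0.150), 0.44 for Rpusd3 (0.248), 0.17 for Fastkd2 (0.158), 0.12 for Trub2 (0.538), 0.04 for Rpusd4 (0.90) and 0.01 for Rcc1l (0.961). The whole list of 8 thus had 1 rise and 1 fall, or 0 rises and 1 fall adjusted over the list alone, and was not called by camera (adjusted p = 0.821); its median was 0.14 and camera placed it higher, while the fry test placed it lower. Of 33 genes for mitochondrial RNA processing, modification and stability, 9 rose, 5 fell and 19 did not pass (camera adjusted p = 0.370), with rises of the tRNA CCA-adding enzyme Trnt1 (1.26), the pseudouridine synthase Pus1 (1.19) and the exonuclease Pde12 (0.86). Of 16 genes for mitochondrial DNA replication and transcription, 0 rose, 3 fell and 13 did not pass (camera adjusted p = 0.536): the falls were Mterf2 (-0.97), Dguok (-0.65) and Rrm2b (-0.52), while the polymerase gene Polg (0.06, edgeR adjusted p = 0.566) and Tfam (0.10, edgeR adjusted p = 0.438) did not pass. Except where another number is given, counts were the same when adjusted over the list alone, here and for the lists that follow.

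Protein genes of the large mitoribosomal subunit split into 15 that rose, 10 that fell and 23 that did not pass of 48 (camera adjusted p = 0.536). Mrpl19 rose by 0.97 on the log2 scale, while Mrpl18 fell by 0.93, Mrpl28 fell by 0.84 and Mrpl42 fell by 0.83. In the small subunit 10 rose, 6 fell and 14 did not pass of 30 (camera adjusted p = 0.758), with Mrps18b at 1.63, Mrps6 at 0.93, Mrps34 at 0.84 and Mrps35 at -0.85. Among 22 factors of mitoribosome assembly and translation, 2 rose, 9 fell and 11 did not pass (camera adjusted p = 0.325); falls included the elongation factor Tufm (-0.73), the ribosome-binding factor Rbfa (-0.61) and the initiation factor Mtif2 (-0.54). Of 17 mitochondrial aminoacyl-tRNA synthetases, 6 rose, 4 fell and 7 did not pass (camera adjusted p = 0.926). Cars2 (-0.91) and Hars2 (-0.55) fell and Tars2 rose (0.51).

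Nuclear genes of oxidative phosphorylation fell together in all of its complexes. Of 36 nuclear complex I subunits, 33 fell, 0 rose and 3 did not pass, with 34 falls adjusted over the list alone and a median log2 fold change of -0.51; Ndufb4 (-0.95), Ndufv3 (-0.87) and Ndufs1 (-0.80) fell most (camera adjusted p = 6.00e-09; adjusted p = 0.0669 with an estimated correlation). All 4 complex II subunits fell, from Sdha (-0.57) to Sdhb (-0.39) (camera adjusted p = 0.0221; adjusted p = 0.161 with an estimated correlation). In complex III 8 of 9 fell and 1 did not pass, with Uqcrq at -1.19 and Uqcr11 at -0.99 (camera adjusted p = 0.000692; adjusted p = 0.161 with an estimated correlation). In complex IV 10 of 12 fell and 2 did not pass, led by the heart and muscle isoform Cox7a1 (-1.68), then Cox8b (-1.03) and Cox6c (-1.02) (camera adjusted p = 0.00458; adjusted p = 0.138 with an estimated correlation). In complex V, the ATP synthase, 13 of 15 fell, 1 rose and 1 did not pass, with Atp5k at -0.86 and Atp5j at -0.83 (camera adjusted p = 0.00109; adjusted p = 0.217 with an estimated correlation).

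Genes of fuel metabolism changed too, with most genes of fatty acid oxidation lower and a mixed change in those of glycolysis. Of 31 genes of fatty acid uptake and oxidation, 26 fell, 3 rose and 2 did not pass (camera adjusted p = 1.54e-06; adjusted p = 0.140 with an estimated correlation). Lipoprotein lipase Lpl fell 3.17-fold (log2 -1.66, SE 0.03), with Ucp3 at -1.65 and Acaa2 at -1.40, while the acyl-CoA thioesterase Acot2 rose (1.57). In the tricarboxylic acid cycle 15 of 19 genes fell, 3 rose and 1 did not pass, with 16 falls adjusted over the list alone; Idh2 (-1.31) and Idh3b (-0.81) fell, and Pdhb rose (0.97) (camera adjusted p = 0.00269; adjusted p = 0.228 with an estimated correlation). Of 24 genes of glycolysis and glucose uptake, 14 rose, 8 fell and 2 did not pass, with 15 rises adjusted over the list alone (camera adjusted p = 0.0928). The glucose transporter Slc2a1 rose 7.28-fold (log2 2.86, SE 0.12), the lactate transporter Slc16a3 rose by 2.28 and Pgam1 by 2.17, while Pfkfb1 fell by 3.36. In lipogenesis 13 of 18 genes fell, 2 rose and 3 did not pass, among them Elovl6 (-1.91), Lpin1 (-1.67), fatty acid synthase Fasn (-1.62) and Mlxipl (-1.51) (camera adjusted p = 0.000692; adjusted p = 0.138 with an estimated correlation). Of 21 genes of cholesterol synthesis 4 rose, 6 fell and 11 did not pass, with 5 falls adjusted over the list alone (camera adjusted p = 0.536), Pmvk (-1.32) and Fdft1 (-0.90) among the falls. Of 13 coenzyme Q genes 2 rose, 5 fell and 6 did not pass (camera adjusted p = 0.464): Coq8a fell by 1.84 and Coq9 fell by 0.76, while Coq8b rose by 1.63 and Coq10b by 1.05.

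Of all lists, targets of the integrated stress response, which halts general translation and induces amino acid genes, had the highest median log2 fold change. Of 33 targets, 32 rose and 1 fell, with a median log2 fold change of 2.49, which stayed at 2.49 with genes at 0 in WT set to their bound (camera adjusted p = 2.95e-18; adjusted p = 0.0200 with an estimated correlation). Several were close to absent in WT. The secreted stress hormone Gdf15 had 939 counts over the 3 KO and 1 over the 3 WT untreated libraries, a ratio of 853 (95% counting interval 153 to 33713; intervals and floors cover counting error only). Fgf21, another stress hormone, had 110 counts in KO and 0 in WT, at least 33.3-fold higher against a floor of 3 counts over the group. The cystine transporter Slc7a11 had 942 counts against 3, a ratio of 285 (95% counting interval 97.3 to 1385), and the cationic amino acid transporter Slc7a3 had 258 against 1, a ratio of 234 (41.7 to 9289). Of 18 genes for the synthesis of serine, glycine, one-carbon units and proline, 13 rose, 2 fell and 3 did not pass (camera adjusted p = 5.77e-05, and adjusted p = 0.138 with an estimated correlation). The mitochondrial folate enzyme Mthfd2 rose 172-fold (log2 7.42, SE 0.16, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.03e-120), Phgdh, which opens serine synthesis, by 5.41 on the log2 scale, Psat1 by 5.31 and the proline enzyme Pycr1 by 4.71.

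Quality control and redox genes also rose. Of 18 mitochondrial chaperones and proteases, 11 rose, 3 fell and 4 did not pass (camera adjusted p = 0.0146; adjusted p = 0.142 with an estimated correlation), led by the matrix protease Lonp1 (2.24, SE 0.05), the chaperonin genes Hspe1 (1.45) and Hspd1 (1.07), and Afg3l2. Of 25 antioxidant and NRF2 target genes, which include Slc7a11, 17 rose, 3 fell and 5 did not pass, with 4 falls adjusted over the list alone (camera adjusted p = 0.00109; adjusted p = 0.112 with an estimated correlation). Heme oxygenase Hmox1 rose by 3.59 on the log2 scale (SE 0.22), Srxn1 by 3.11 and Txnrd1 by 2.18. Mitochondrial dynamics and mitophagy went both ways, with 5 of 16 genes higher, 10 lower and 1 not passing (camera adjusted p = 0.319): the autophagy receptors Sqstm1 (2.44) and Optn (1.51) and Gabarapl1 (1.09) rose, and the kinase Pink1 fell (-1.43). Among 25 genes of mTOR signalling and autophagy regulation 10 rose, 9 fell and 6 did not pass, with 10 falls adjusted over the list alone; the median was -0.01 although camera placed the list higher, without a call (adjusted p = 0.716). Sesn2 (4.05), Irs2 (2.46) and Eif4ebp1 (2.40) rose and the ubiquitin ligase Fbxo32 fell (-1.35).

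Contractile and ion channel genes of the adult cardiomyocyte fell. Of 27, 23 fell, 2 rose and 2 did not pass, with a median of -1.04 (camera adjusted p = 1.37e-09; adjusted p = 0.0280 with an estimated correlation). Phospholamban, Pln, a regulator of the calcium pump, fell 5.02-fold (log2 -2.33, SE 0.03), and the potassium channel genes Kcnj3 (-2.72), Kcnj2 (-2.38) and Kcnip2 (-1.96) fell as well. In the cardiac stress and fetal program 10 of 18 genes rose, 6 fell and 2 did not pass (camera adjusted p = 0.0652). The natriuretic peptide Nppb rose 11.1-fold (log2 3.48, SE 0.04), Fhl1 9.53-fold and the beta myosin heavy chain Myh7 6.03-fold, while Mybpc2 fell by 2.53. Genes of the extracellular matrix and fibrosis rose in 25 of 32 cases, with 2 falls and 5 that did not pass (camera adjusted p = 2.76e-07; adjusted p = 0.0669 with an estimated correlation). Tenascin C, Tnc, rose 28.1-fold (log2 4.81, SE 0.17), Ccn2 12.4-fold, Timp1 9.16-fold and Thbs1 6.96-fold.

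**Figure D2:**
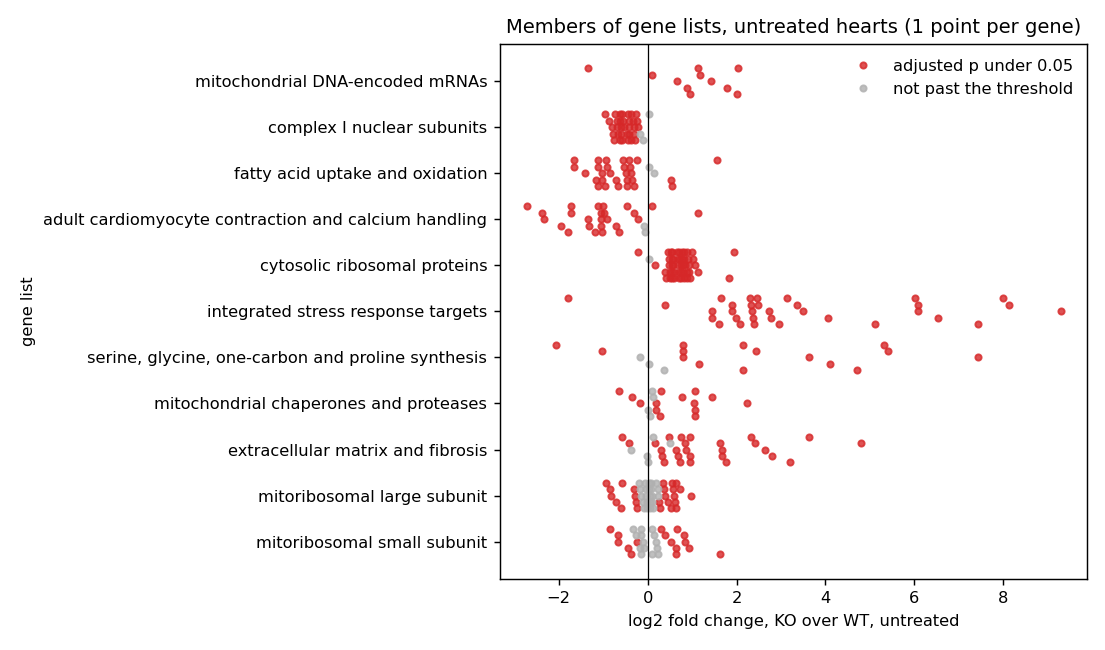
Log2 fold change of each tested member of 11 gene lists in untreated KO against WT hearts (n = 3 per group), red where the edgeR Benjamini-Hochberg adjusted p was under 0.05 and grey otherwise. Stress response targets lie mostly above 0, with 32 of 33 higher, and complex I subunits below, with 33 of 36 lower; fitted values of genes with 3 or fewer counts in WT, such as Gdf15 and Fgf21, are no bounds.

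Genes of growth and death programs changed as well. Of 51 cytosolic ribosomal protein genes, 49 rose, 1 fell and 1 did not pass, with a median of 0.70 (camera adjusted p = 9.91e-14; adjusted p = 0.0280 with an estimated correlation); Rps16 (1.95), Rpl3 (1.82) and Rpl24 (1.14) were among the rises, and such genes can share reads with pseudogenes. Apoptosis and p53 targets rose in 11 of 16 cases, with 2 falls and 3 that did not pass (camera adjusted p = 0.0106; adjusted p = 0.140 with an estimated correlation), among them Tnfrsf12a (3.06), the cell cycle inhibitor Cdkn1a (2.84), Gadd45g (2.47) and Phlda3 (2.08). Of 11 cell cycle genes 6 rose, 1 fell and 4 did not pass (camera adjusted p = 0.0245; adjusted p = 0.161 with an estimated correlation), with Tpx2 at 2.24, Ccna2 at 1.83, Mki67 at 1.39 and Top2a at 1.36. Type I interferon genes included 7 of 16 that rose, 0 that fell and 9 that did not pass, with Irf7 at 0.73, Stat2 at 0.69 and Oasl2 at 0.63 (camera adjusted p = 0.0652). That list was called without KO_untreated replicate 2 (camera adjusted p = 0.0232), WT_untreated replicate 2 (0.0281) or WT_untreated replicate 3 (0.0227), and with mitochondrial genes left out (0.0399).

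Markers of the other cells of the heart did not all move in the same direction. Macrophage and monocyte markers rose in 7 of 11 cases, with 0 falls and 4 that did not pass, including Cd68 (1.02), C1qa (0.64) and C1qc (0.63). Camera called that list (adjusted p = 0.0402; adjusted p = 0.186 with an estimated correlation), but not without KO_untreated replicate 3 (adjusted p = 0.0529) or WT_untreated replicate 2 (0.0522). Adipocyte markers fell in 5 of 6 cases, with Adipoq (-1.22), Ucp1 (-1.16), Plin1 (-0.94) and Cfd (-0.63) lower (camera adjusted p = 0.0397; adjusted p = 0.206 with an estimated correlation; 0.0517 without KO_untreated replicate 1). Endothelial markers had 4 rises, 4 falls and 4 that did not pass of 12 (camera adjusted p = 0.721), with Eng (0.66), Esam (0.47) and Flt1 (0.40) higher and Tek (-0.52) lower. Fibroblast markers had 3 rises, 4 falls and 2 that did not pass of 9 (camera adjusted p = 0.536), with Mfap5 (1.27) and Col1a1 (0.64) higher and Gsn (-0.89) and Pdgfra (-0.64) lower. In smooth muscle and pericytes 6 of 11 markers fell, 1 rose and 4 did not pass (camera adjusted p = 0.0725), with Abcc9 at -1.27, Smtn at -1.04, Myh11 at -0.68 and Kcnj8 at -0.54. Atrial markers had 5 falls, 2 rises and 1 that did not pass of 8 (camera adjusted p = 0.278); Sln (-2.75) and Myl7 (-2.03) fell and Bmp10 rose (2.19).

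Smaller marker lists complete the picture in untreated libraries. Erythroid markers fell in 4 of 5 cases, Hbb-bt by 0.77 and Hbb-bs by 0.42 among them (camera adjusted p = 0.152). Hba-a1, at -0.22, was 1 of the 4, but its call was lost with DESeq2 (adjusted p = 0.641), with all 12 libraries in 1 edgeR fit (0.0925) and without KO_untreated replicate 1 (0.729), and its sign turned without WT_untreated replicate 3 (0.10). Of 3 epicardial markers, Upk3b (-1.40) and Msln (-1.11) fell and Wt1 did not pass (0.16, edgeR Benjamini-Hochberg adjusted p = 0.677; camera adjusted p = 0.248 for the list). Of 3 Schwann cell and neuron markers 2 fell and 1 did not pass (camera adjusted p = 0.102): Dbh had 2 counts in KO and 39 in WT, a ratio of 21.5 (95% counting interval 5.56 to 184), and Mbp at -0.46 passed only without WT_untreated replicate 3 (edgeR adjusted p = 0.0467). Lists with 2 tested members had no camera test: in B cells Ighm fell (-1.42) and Igkc did not pass (0.29, edgeR adjusted p = 0.426), and in skeletal muscle Acta1, also a fetal heart gene, rose (2.37) and Ckm fell (-0.64). Neutrophil and T or NK cell markers had no member with enough counts to test. Of 9 residual ribosomal and small structural RNAs 3 rose, 3 fell and 3 did not pass, with 4 falls adjusted over the list alone (camera adjusted p = 0.997; median -0.04, placed lower by camera and higher by fry): Gm26917 (0.81) and Rpph1 (0.49) rose, and Rn7sk (-0.59) and Rn7s1 (-0.44) fell.

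Single genes beyond the lists also differed. The largest rises without any WT counts were Vmn2r3, annotated as a vomeronasal receptor of a large family, at least 287-fold higher (948 counts against 0, floor of 3 counts over the group), the muscle hormone gene Ostn, at least 100.2-fold, Fam227b, at least 64.8-fold, Cyb5r2, at least 39.953-fold, Akr1b7, at least 39.3-fold, Fibcd1, at least 35.1-fold, and Cdsn, at least 34.5-fold. Among named genes with more than 3 counts in KO, the deepest falls on the log2 scale were those of the water channel Aqp4 (-5.16, SE 0.40), Efnb3 (-4.84, SE 0.26), the muscle gene Ky (-4.63, SE 0.29), the receptor Gpr22 (-4.57, SE 0.15), Pla2g4e (-4.39, SE 0.42), Sbk3 (-4.19, SE 0.13), the potassium channel subunit Kcnv2 (-4.11, SE 0.34), Smim5 (-4.10, SE 0.49) and Gal3st3 (-4.06, SE 0.50). The chloride channel Clcn1 had 3 counts in KO and 138 in WT, 50.7 times lower (95% counting interval 16.98 to 249). Together 7079 of 12228 genes differed in untreated hearts, 3571 higher and 3508 lower (edgeR quasi-likelihood test, Benjamini-Hochberg), 1990 of them by at least 2-fold. By camera 20 of the 43 lists with at least 3 tested members were called, 10 higher and 10 lower, and 3 calls held with an estimated correlation: stress response targets, adult cardiomyocyte genes and cytosolic ribosomal proteins.

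KO and WT libraries also differed in sex-linked RNA. Xist, the RNA of the inactive X chromosome, had 3020 counts over the 3 KO and 1 over the 3 WT untreated libraries, a ratio of 2742 (95% counting interval 492 to 108348). At the same time each KO library held transcripts of the Y chromosome, which fell in KO, with log2 fold changes of -1.02 for Uty, -0.90 for Kdm5d, -0.58 for Eif2s3y and -0.47 for Ddx3y. After CMC these were -1.01, -0.86, -0.13 (not passing, edgeR adjusted p = 0.227) and -0.28. The untreated list of 5 thus had 1 rise and 4 falls (camera adjusted p = 0.248; median -0.58, placed lower by camera and higher by fry). With genes on the X and Y chromosomes left out, 6862 of 11835 genes differed, 3455 higher and 3407 lower.

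**Figure D3:**
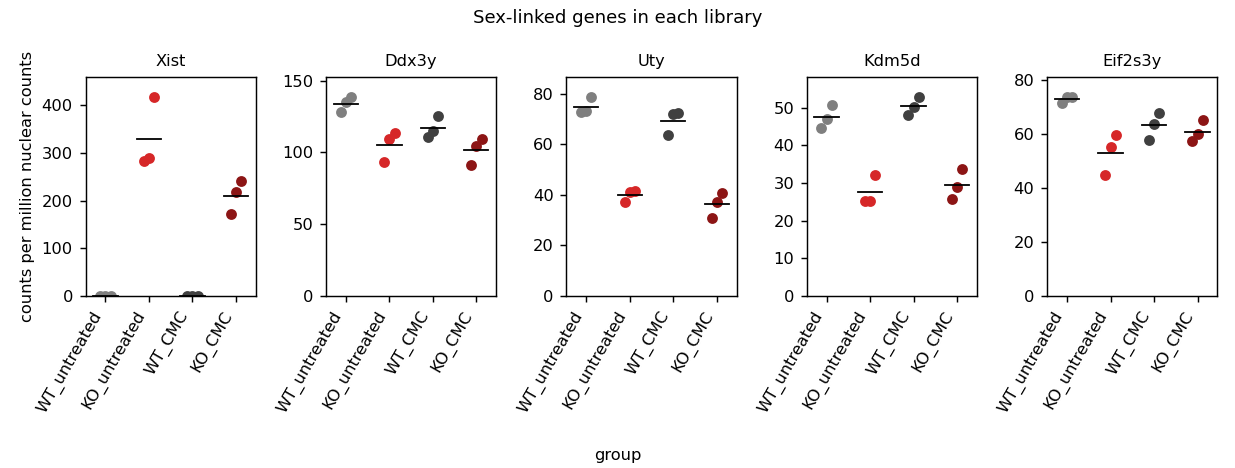
Counts per 1000000 nuclear counts of Xist and of 4 Y-linked genes in each library (points), with the group mean (line), n = 3 per group. Xist is at 0 or close to it in every WT library, with a mean of 330 in KO untreated and 210 in KO after CMC, and all 4 Y-linked genes are present in all 12 libraries.

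The same genotype comparison in the CMC libraries asks whether the chemical treatment alters the picture, and it called many of the same genes. Ptcd1 fell by 1.96 on the log2 scale (SE 0.19, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.83e-10). mt-Rnr2 fell by 2.78, mt-Rnr1 rose by 1.96, and rises of mt-Nd2 (2.58), mt-Nd1 (2.52), mt-Nd3 (2.22), mt-Cytb (1.51) and mt-Nd5 (0.61) were seen, with mt-Nd6 at -0.96. Counts of genes called in KO against WT were 6591 of 12144, 3292 higher and 3299 lower, 1996 of them by at least 2-fold, or 6389 of 11757 without X and Y genes. Of 11912 genes tested in both treatments, 2738 were higher in both and 2642 lower in both, where independent lists would share 959 and 930, and 16 had opposite directions; across genes the log2 fold changes had r = 0.937, and genes are not independent replicates. The labels number the untreated and CMC libraries of each genotype alike, so this overlap cannot be taken as a repeat in other animals. Whether both treatments used RNA of the same animals is not given in the sources used here.

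Genes named by the same rule after CMC were again led by Vmn2r3, at least 244-fold higher, Ostn, at least 88.7-fold, Slc7a3, at least 72.0-fold, Akr1b7, at least 45.4-fold, Cdsn, at least 37.9-fold, and Sh2d6, at least 36.8-fold, with Adm2 and Soat2 each at least 30.02-fold higher, all against 0 counts in WT. Gdf15 had a ratio of 953 (95% counting interval 171 to 37668) and Slc7a11 of 783 (140 to 30959). The falls were Ky (-4.90), Cilp2 (-4.74), Gpr22 (-4.43), Efnb3 (-4.18), Sbk3 (-4.10), Kcnv2 (-4.07), the vessel growth factor Angpt1 (-3.89), Smco1 (-3.80) and Clcn1 (-3.74), while Gal3st3 was 41.0 times lower (95% counting interval 11.0 to 344). Among 16S factors Rpusd4, a pseudouridine synthase, was at -0.67 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0479), a call lost without KO_CMC replicate 1 (0.145), KO_CMC replicate 2 (0.0673), KO_CMC replicate 3 (0.111) or WT_CMC replicate 1 (0.344), and with DESeq2 (0.164). Ngrn (0.31, edgeR adjusted p = 0.115) passed without KO_CMC replicate 2 (0.0432), and Fastkd5 (0.63, edgeR adjusted p = 0.0652) without WT_CMC replicate 1 (0.0380). By camera 20 of 43 lists were called and 18 lists were called in both treatments. Smooth muscle and pericyte markers (camera adjusted p = 0.0258) and erythroid markers (0.0190) were called after CMC only, a difference that was not tested. Both calls were lost with an estimated correlation (camera adjusted p = 0.169 and adjusted p = 0.206 with an estimated correlation). Macrophage markers (camera adjusted p = 0.0527) were not called, but were without KO_CMC replicate 1 (0.0346), KO_CMC replicate 2 (0.0395), WT_CMC replicate 1 (0.0350) or WT_CMC replicate 2 (0.0324), and with a replicate block (0.0462). Adipocyte markers (0.0617) were called by camera without WT_CMC replicate 3 (0.0248). Interferon genes (0.0517) were called by camera without KO_CMC replicate 1 (0.0401), KO_CMC replicate 2 (0.0203) or WT_CMC replicate 3 (0.0464), and with a replicate block (0.0375). Schwann cell and neuron markers (0.0595) were called by camera without KO_CMC replicate 1 (0.0343), 2 (0.0302) or 3 (0.0174), or WT_CMC replicate 1 (0.0435) or 3 (0.0234). With an estimated correlation 4 held: stress response targets (adjusted p = 0.0199), adult cardiomyocyte genes (0.0327), complex I (0.0327) and cytosolic ribosomal proteins (0.0225).

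CMC itself changed gene counts mostly by less than 2-fold. The counts of calls in WT and KO are not a test of a difference, since the biological coefficient of variation was 5.23% in the WT and 3.01% in the KO comparison. In WT 260 of 12098 genes differed between CMC and untreated libraries, 110 higher and 150 lower, 39 of them by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). The glycolysis gene Gapdh (-0.82, edgeR adjusted p = 2.61e-11) and mt-Nd6 (-1.02) fell and Ubald2 rose (1.101), though not called without WT_untreated replicate 2 (adjusted p = 0.0792). The other genes of the naming rule were Scarf2 (1.247), Cebpb (1.15), H2afj (1.002), Cebpd (0.97), Zfp992 (-1.28), Sowahc (-1.15) and Sec61a2 (-0.78), and each lost its call without at least 4 of the 6 libraries taken in turn, with edgeR adjusted p values up to 0.307. The WT count was 110 without WT_CMC replicate 1, 743 without WT_CMC replicate 3, and 70, 99 and 139 without WT_untreated replicates 1, 2 and 3. In KO 1461 of 11911 genes differed, 815 higher and 646 lower, 69 by at least 2-fold; mt-Tm (1.27) and Ubald2 (1.07) rose and Nup35 (-1.13) fell. Zfp628 (1.14) was not called without KO_untreated replicate 1 (edgeR adjusted p = 0.0624), and Micall2 (1.07), Car7 (1.05), Timm8a1 (-1.21), Cbx2 (-1.05), Ppih (-1.04) and Zfp119a (-1.04) each lost their call without at least 2 of the 6 libraries, with edgeR adjusted p values up to 0.217. Of 11380 genes tested in both, 40 were higher in both and 73 lower in both, against 7.67 and 8.19 for independent lists, with 6 in opposite directions.

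The CMC effect itself differed between the genotypes for 187 of 12788 genes, 137 with a positive and 50 with a negative difference of KO minus WT (edgeR quasi-likelihood, Benjamini-Hochberg). Mitochondrial mRNAs were among them: mt-Nd2 rose with CMC by 0.63 on the log2 scale in KO and stood at 0.05 in WT, a difference of 0.58 (SE 0.09, edgeR adjusted p = 7.45e-05), and mt-Cytb differed by 0.57, mt-Nd5 by 0.52 and mt-Nd1 by 0.50. The transcription regulator Id3 differed by -1.34 (SE 0.24, edgeR adjusted p = 0.000441). The count rested on single samples: it was 66, 66 and 113 without KO replicates 1, 2 and 3, and 56, 59 and 562 without WT replicates 1, 2 and 3. WT_CMC replicate 3 stood apart from the other WT_CMC libraries, with a replicate chi-square over nuclear genes of up to 2.43 per degree of freedom in that group and at most 1.36 in the others.

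Because CMC marks pseudouridine, its traces in the reads can show modified bases of mitochondrial RNA, and a difference between KO and WT after CMC lay inside the 16S rRNA. In mt-Rnr2, position 2509 of the mitochondrial genome, a T that is base 1416 of the gene, was skipped in 36.6 ± 12.9 (SD, n = 3) of 10000 reads in WT after CMC and in 7.64 ± 1.68 in KO after CMC. In untreated libraries it was skipped in 0.309 ± 0.0666 of 10000 reads in WT and 0.0839 ± 0.145 in KO. It was the position of mt-Rnr2 with the smallest p between KO and WT after CMC. The KO rate after CMC was 4.76-fold lower (log2 ratio -2.25, SE 0.30, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000356), and the call held without each of the 6 libraries in turn. Other positions with more deletions after CMC in both genotypes were also lower in KO, with a median log2 ratio of -0.64 over 744. WT_CMC replicate 3 did not share this: scale factors from those positions were 1.30, 1.58 and 0.875 in WT_CMC replicates 1, 2 and 3. In the KO libraries after CMC they were 0.741 to 0.883. With each library scaled by those positions, a test added after the data were seen, 2509 was 3.12-fold lower (log2 ratio -1.64, SE 0.24, edgeR adjusted p = 6.12e-05). It was not alone: the scaled test called 22 of 2512 positions, 13 of them lower in KO. Before scaling, 4 of the 744 had a ratio as low as that of 2509, and 0 of the 250 with at least 5 deletions per 10000 reads. The sequence around it, from 2499 to 2519, is CTACGTGATCTGAGTTCAGAC. Deletions at 2509 rose with CMC in WT by 6.86 log2 units and in KO by 5.98, each in a fit of its own 6 libraries. In the fit of all 12 the difference of these effects was -0.48 (SE 1.74, edgeR adjusted p = 0.979), but the untreated KO libraries held 0, 0 and 1 deletions there, too few for this test to decide. At least 22361 reads covered the position in each KO and 108308 in each WT library after CMC.

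**Figure D4:**
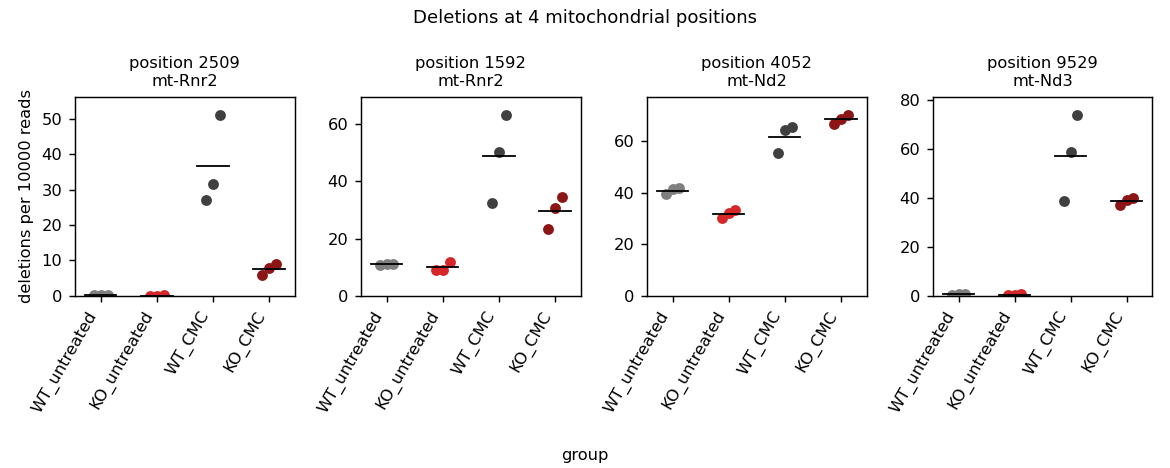
Deletions per 10000 reads at 4 mitochondrial positions in each library (points) with the group mean (line), n = 3 per group. At 2509 the WT libraries after CMC average 36.6 and those of KO 7.64. The same groups average 48.7 and 29.5 at 1592 in mt-Rnr2, 57.2 and 38.8 at 9529 in mt-Nd3, and 61.7 and 68.4 at 4052 in mt-Nd2. At 4052 untreated libraries already average 40.8 in WT and 31.8 in KO.

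Other positions gained deletions with CMC in both genotypes. Among positions called higher with CMC in both, the mean over KO and WT after CMC was highest at 4052, an A in mt-Nd2. It stood at 61.7 ± 5.61 (SD, n = 3) per 10000 reads in WT and 68.4 ± 1.78 in KO, where untreated libraries had 40.8 ± 1.32 and 31.8 ± 1.56. By the same mean, next came 9529, a T in mt-Nd3, at 57.2 ± 17.7 (SD) per 10000 reads in WT and 38.8 ± 1.37 in KO after CMC, and 7264, an A in mt-Co2, at 45.8 ± 5.52 and 42.4 ± 2.36. The neighbouring 7263 held the same deletion counts as 7264 in untreated KO, 264, 261 and 233. Neighbouring positions may thus share deletions, and counts of positions need not be counts of separate sites. In mt-Rnr2, 1592 stood at 48.7 ± 15.5 and 29.5 ± 5.74. The test of deletions alone was added after the data were seen. It called 1217 of 1783 positions with CMC in WT, all higher, and 1051 of 1994 in KO, 1050 higher and 1 lower (edgeR quasi-likelihood with depth as an offset, Benjamini-Hochberg). Between KO and WT after CMC 29 of 2512 positions differed, 27 of them lower in KO, but the count was 2 without KO_CMC replicate 1, 2 or 3 or WT_CMC replicate 1, 3 without WT_CMC replicate 2 and 684 without WT_CMC replicate 3. Between untreated KO and WT 6 of 1219 positions differed, 2 higher and 4 lower in KO, and the count was 3 without KO_untreated replicate 2, 2 without KO_untreated replicate 3 and 3 without WT_untreated replicate 1. The CMC effect differed between genotypes at 8 of 3027 positions, all lower in KO. That count was 1, 1 and 2 without KO replicates 1, 2 and 3, and 2, 2 and 124 without WT replicates 1, 2 and 3.

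Mismatches and deletions together, the measure chosen beforehand, gave no call between KO and WT at the minimum share chosen beforehand, but did at a lower one. Among positions with a mean variant share of at least 1%, limma called 0 of 21 between untreated KO and WT, 0 of 22 after CMC, 0 of 27 for CMC in WT and 0 of 20 for the difference of CMC effects, with 5, 1, 3 and 1 at an unadjusted p under 0.05. A quasi-binomial model called 1 of the 27 for CMC in WT, at 6068 (adjusted p = 0.0200), and 0 in the other 3. In KO 5 of 21 positions differed with CMC by limma, at 12636 (0.53 on the log2 odds scale), 5172 (0.37), 13087 (-0.36), 6068 (-0.26) and 6631 (-0.20), each with adjusted p = 0.0365; with a minimum mean share of 0.1%, and more positions tested, 6631 alone of these kept its call. The count of called positions, not always among these 5, was 1, 0 and 3 without KO_CMC replicates 1, 2 and 3, and 1, 0 and 0 without KO_untreated replicates 1, 2 and 3. The untreated count was 1 without WT_untreated replicate 1, and the count for the difference was 1 without KO replicate 1 or WT replicate 3. Every library read another base than the reference at 3 positions, 4528 and 4891 in mt-Nd2 and 9461 in mt-Nd3, in 99.6 to 100% of reads.

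With a minimum mean share of 0.1%, tried after the data were seen, limma called 12 of 8759 positions between untreated KO and WT, 4 higher and 8 lower in KO, and 3 of 9496 after CMC, 2 higher and 1 lower (Benjamini-Hochberg). The 3 called in both treatments, named after their values were seen, were 4658 in mt-Nd2, 8861 in mt-Co3 and 2656 in mt-Rnr2. At 4658 the variant share in untreated libraries was 0.0992% ± 0.00819 (SD, n = 3) in KO and 1.38% ± 0.28 in WT (log2 odds -3.80, limma adjusted p = 2.89e-08), and 0.132% ± 0.00747 and 1.41% ± 0.220 after CMC (-3.42, limma adjusted p = 0.000319). At 8861 it was 0.693% ± 0.181 in KO and 0.0672% ± 0.0237 in WT untreated libraries (3.37, limma adjusted p = 1.55e-05), and at 2656 it was 0.247% ± 0.0361 and 0.0125% ± 0.00957 (4.44, limma adjusted p = 1.55e-05). Calls at 4658 and 8861 held without each library in turn in both treatments, while 2656 was under the minimum share without KO_untreated replicate 3 or KO_CMC replicate 2. Each of the other 9 untreated calls was lost, or under the minimum share, without at least 1 library.

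Steps in read depth, where reverse transcription could stop 1 base before a CMC adduct, were compared base by base. With CMC 2287 of 14780 steps differed in WT and 8003 of 14912 in KO (limma, Benjamini-Hochberg), with a median change of 0.0123 and 0.00818 log2 units among those called, and 59 and 145 of them changed by at least 0.1. Between KO and WT after CMC 141 of 14753 steps differed, 74 higher and 67 lower, and 42 of them lay within 151 bases of a position at the depth limit. The largest named steps were at 2657 (1.17) and 2660 (0.98), near the 3' end of mt-Rnr2, and at 1347 (-1.04) within it, the last of which was not called with a replicate block (limma adjusted p = 0.0645). Leaving out libraries moved that count to 31, 21 and 24 without KO_CMC replicates 1, 2 and 3, and to 37, 57 and 3533 without WT_CMC replicates 1, 2 and 3. The CMC effect on steps in WT was called at 1213 without WT_CMC replicate 1, 5012 without WT_CMC replicate 3, and 562, 765 and 492 without WT_untreated replicates 1, 2 and 3. The effect differed between genotypes at 271 of 14749 steps, or at 103, 71 and 67 without KO replicates 1, 2 and 3 and 103, 139 and 5026 without WT replicates 1, 2 and 3.

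The authors' own comparison of untreated libraries, deposited as a table of 51888 genes, called 4967 at an adjusted p under 0.05, 2589 higher and 2378 lower in KO. Of these 4789 were tested here, and all 4789 were called in the same direction by edgeR. Their table gives log2 fold changes of -2.91 for mt-Rnr2, 1.94 for mt-Rnr1 and -1.93 for Ptcd1. In the authors' gene ontology tables, the mitochondrion held 719 called genes of 1718 (p = 1.50e-103), translation 266 of 588 (p = 2.99e-49), the cytosolic ribosome 87 of 108 (p = 1.08e-51), contractile fibers 136 of 216 (p = 1.74e-33) and heart contraction 110 of 198 (p = 8.57e-22), as the authors computed them.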

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

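All tests of explanations here were chosen only after the result was seen, as were the test of deletions alone and the counts over other splits of the samples.

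CMC effects that differed between KO and WT were the results singled out for a closer look, all by a test of the difference itself. In genes the difference was called 187 times by edgeR. The CMC effect in KO minus that in WT was positive for Spa17 (log2 2.07, edgeR adjusted p = 0.0323), Sowahc (1.4998, 0.0336), Zscan29 (0.87, 0.0470), Pqbp1 (0.87, 0.00490) and Rp9 (0.81, 0.00221), and for mt-Nd2 (0.58), mt-Cytb (0.57), mt-Nd5 (0.52, not called with DESeq2) and mt-Nd1 (0.50). It was negative for Id3 (-1.34), Mrpl36 (-1.20), Ctdnep1 (-0.88), Aar2 (-0.85) and Pskh1 (-0.75). A positive difference can come from a fall in WT, as for Sowahc, at -1.15 in WT and 0.35 in KO. Calls of Pqbp1 were lost without WT replicates 1 or 2 (edgeR adjusted p up to 0.0816) and of Rp9 without WT replicate 2 (0.0707). Those of Spa17, Sowahc, Zscan29, Mrpl36, Ctdnep1, Aar2 and Pskh1 were lost without at least 4 of the 6 replicates taken in turn, with edgeR adjusted p up to 0.445. The gene count was 66, 66 and 113 without KO replicates 1, 2 and 3 and 56, 59 and 562 without WT replicates 1, 2 and 3.

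Depth steps with a different CMC effect numbered 271, with the named positions all in mt-Rnr2. Their log2 differences were -0.0128 at 1175, -0.0253 at 1178, -0.0303 at 1186, 0.0246 at 1246, 0.0431 at 1249, 0.0641 at 1252, 0.125 at 1255, 0.150 at 2502, -0.0175 at 2520 and -0.0298 at 2525. That count was 103, 71 and 67 without KO replicates 1, 2 and 3 and 103, 139 and 5026 without WT replicates 1, 2 and 3. Deletions with a different CMC effect numbered 8, including 1152 (log2 -1.95), 1275 (-1.52), 1564 (-2.04), 1895 (-2.21) and 1934 (-1.71) in mt-Rnr2. Calls at 1275, 1564 and 1934 were each lost without 5 of the 6 replicates taken in turn (edgeR adjusted p up to 0.320). The call at 1152 was lost without KO replicate 1 or 2 (edgeR adjusted p up to 0.114). Without KO replicates 1, 2 and 3 there were 1, 1 and 2, and without WT replicates 1, 2 and 3 there were 2, 2 and 124. Insertions, which no comparison used, reached 9.91 per 1000000 bases of mitochondrial depth in WT after CMC (7.22 to 12.7 over its libraries), above 6.27 ± 0.220 (SD, n = 3) in untreated WT. In KO they stood at 7.24 ± 0.300 after CMC and 7.06 ± 0.0612 untreated. No difference of insertions was tested.

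For the differences of CMC effects, 3 of 40 splits of the samples gave as many genes as the real 187, the highest other being 310. For steps 3 of 40 gave as many as 271, with 3059 as the highest other, and for deletions 6 of 40 gave as many as 8, with 935 as the highest other. For variant shares all 40 splits gave as many as the real 0, with up to 4. Splits with many more calls point to a structure of the samples, since exchanging CMC labels within a genotype brings the CMC effect itself into the difference. These splits are thus no reference free of an effect, and they cannot decide whether chance gave the counts, which was not excluded.

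With 10 splits of 6 samples no share under 0.05 can be had, and 1 split, the real 1, gave as many in each comparison named next. The real count and the highest other were 7079 and 0 for genes in untreated KO against WT, 6591 and 0 after CMC, 260 and 0 for CMC in WT, and 1461 and 0 for CMC in KO. For lists they were 20 and 12 in both treatments, for mitochondrial gene depth 37 and 0, and 32 and 0 after CMC, and for junctions 24 and 0. They were 5 and 0 for variant shares with CMC in KO, and for steps 141 and 1 between genotypes, 2287 and 0 for CMC in WT and 8003 and 0 for CMC in KO. For deletions they were 6 and 0 untreated, 29 and 23 after CMC, 1217 and 0 for CMC in WT and 1051 and 0 for CMC in KO. For the other 3 comparisons of variant shares the real count was 0 and all 10 splits gave as many, with up to 1. In each of these comparisons every split other than the real 1 mixed libraries of both groups on each side. A difference between the groups then adds to the spread within each side, which can lower the calls. The counts of the other splits are thus no reference free of an effect. They cannot decide whether chance gave the real counts.

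The fall of mt-Rnr2 with a rise of other mitochondrial transcripts was weighed against 3 technical explanations. Depth set free by lost 16S counts would raise nuclear genes alike, but the nuclear share of counts in KO was 0.980 of that in WT. Unequal removal of ribosomal RNA would move both mitochondrial rRNAs the same way, but the log2 fold changes of mt-Rnr1 and mt-Rnr2 differed by 4.85. The depth limit lowers mt-Rnr2 depth in WT and can only make the fall from depth smaller, so the value from counts minus that from depth, -0.15, decides nothing, and the fall named here was measured on counts. A change in the RNA itself in KO hearts stays open as a hypothesis, found and tested on the same data.

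Fewer deletions at 2509 of mt-Rnr2 in KO after CMC were weighed against a weaker CMC reaction as the whole cause and against the depth limit. Other CMC-dependent positions were lower in KO too, with a median log2 ratio of -0.64 over 744 and -0.51 over the 250 with at least 5 deletions per 10000 reads, but with each library scaled by the 744 positions 2509 stayed lower (-1.64, SE 0.24, edgeR adjusted p = 6.12e-05 over 2512 positions, and up to 0.0430 without single libraries), so a general difference in reaction stays open for a part of the fall alone. That general difference was not shared by WT_CMC replicate 3, whose scale factor of 0.875 lay within the 0.741 to 0.883 of the KO libraries. The scaled test called 22 positions, 13 of them lower in KO, so 2509 was not alone in staying lower. Within 151 bases, the length of a read, the highest depth in a WT library after CMC was 723717, under the 900000 taken as the limit, which argues against the depth limit. A lower share of pseudouridine at that base in KO, among the 16S RNA that is left, stays open as a hypothesis, found and tested on the same data. CMC can also mark other bases and the libraries hold no unmodified standard, so the modification itself was not measured.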

How the results depend on the processing

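Settings that left out X and Y genes or positions near the depth limit, a minimum variant share of 0.1%, deletions alone and their scaling by other CMC-dependent positions, were tests chosen only after the result was seen; the others were planned. Of 122 counts under alternatives other than leaving out libraries, 83 stayed within 1.5 times and 39 moved; of 2959 values of named genes and positions, 2829 stayed on their side of the threshold, 86 lost and 44 gained a call. Without single libraries 92 of 144 counts stayed and 52 moved, and of 3349 named values 3117 stayed, 198 lost and 33 gained a call and 1 reversed: Hba-a1, at -0.22 in KO against WT untreated, was 0.10 without WT_untreated replicate 3 and -0.39 without WT_untreated replicate 1. The cause was not tested for any of these, except where fewer genes or libraries were tested.

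A 2-fold minimum gave 1990 genes untreated, 1996 after CMC, 39 for CMC in WT, 69 for CMC in KO and 10 for the difference of effects. An adjusted p under 0.01 gave 106, 833 and 75 for the last 3, DESeq2 gave 76, 589 and 98, and all 12 libraries in 1 fit gave 436 for CMC in WT. For lists an estimated correlation left 3 untreated and 4 after CMC, and fry called 37 and 35. Gene counts in place of depth called 16 of 16 and 15 of 15 mitochondrial genes, with fewer genes tested. For variant shares the quasi-binomial model gave 1 for CMC in WT and 1 in KO, where mismatches only and the replicate block gave 0. A minimum share of 0.1%, with more positions tested, gave 12 untreated, 3 after CMC, 897 for CMC in WT and 1932 in KO. Deletions alone gave 6, 29, 1217, 1051 and 8 in the order untreated, after CMC, CMC in WT, CMC in KO and difference. For steps between genotypes the mean of 3 bases gave 370, and leaving out the depth limit 73. The mean of 3 bases gave 4674 for CMC in WT and 1772 for the difference, where leaving out the limit gave 146.

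The replicate numbers were also used as a block. Over 18 pairs of libraries r ran from -0.0347 to 0.0105, with 5 of 18 best with their own number. Most of these pairs joined a KO with a WT library. Between untreated and CMC libraries of the same genotype r was 0.00284 to 0.0105 in KO and -0.0183 to -0.0146 in WT. Since untreated replicates differed only somewhat beyond counting error, such low r cannot decide whether the numbers pair libraries. With the block 5 steps were called between genotypes, 314 for CMC in WT and 108 for the difference, and 7039, 6430, 257, 1433 and 161 genes in the 5 comparisons.

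Leaving out each library in turn gave 6659 to 6738 genes untreated, 6073 to 6546 after CMC, 70 to 743 for CMC in WT, 1021 to 1307 in KO and 56 to 562 for the difference. Lists ran from 19 to 21 and from 21 to 23, gene depth from 36 to 37 and 32 to 33, and junctions from 20 to 24. Variant shares ran from 0 to 1 untreated, 0 to 0 after CMC and for CMC in WT, 0 to 3 in KO and 0 to 1 for the difference. Steps ran from 21 to 3533, 492 to 5012, 6144 to 8879 and 67 to 5026, and deletions from 2 to 6, 2 to 684, 880 to 1232, 808 to 975 and 1 to 124. Nuclear depth of 2683284 to 3187748 counts limits small changes of nuclear genes.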

Other observations

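Of the tests here, that of distance from WT was written before its result was seen and that of X-linked genes after it.

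Single deletion sites in mitochondrial RNA also differed without CMC. At 13060, a T in mt-Nd5, deletions reached 42.0 ± 8.84 (SD, n = 3) per 10000 reads in untreated KO and 5.31 ± 0.469 in untreated WT, and 46.1 ± 9.77 and 4.27 ± 1.42 after CMC (log2 ratio 2.96, edgeR adjusted p = 3.47e-18 untreated, and 3.39, 1.86e-05 after CMC). At 13053 nearby, the values were 24.3 ± 5.09 in KO and 21.2 ± 3.27 in WT untreated, and 28.1 ± 4.75 and 32.1 ± 6.27 after CMC. At 4239 the untreated log2 ratio was -1.87 (edgeR adjusted p = 1.00e-06). At 15159 it was -1.99, a call lost without KO_untreated replicate 3 or WT_untreated replicate 3 (edgeR adjusted p up to 0.126), and at 10418 it was -1.24, lost without 3 of the 6 libraries (edgeR adjusted p up to 0.334).

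Deletions over the whole mitochondrial genome were also higher with CMC in each genotype, while mismatches showed no such shift beyond the spread between libraries. Deletions per 1000000 bases were 20.04 ± 0.0188 (SD, n = 3) in untreated KO, 21.1 ± 0.541 in untreated WT, 52.7 ± 3.98 in KO after CMC and 85.0 ± 23.9 in WT after CMC. WT_CMC replicates 1, 2 and 3 stood at 88.2, 107 and 59.7, so replicate 3 lay close to the KO libraries after CMC, at 48.2 to 55.6. Mismatches per 1000000 bases, outside the 3 positions where every library differs from the reference, were 1203 ± 23.8 in untreated KO and 1249 ± 48.2 in KO after CMC, and 1143 ± 79.1 in untreated WT and 1339 ± 263 in WT after CMC, where replicate 1 stood at 1642 and replicates 2 and 3 at 1201 and 1174.

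Xist and transcripts of the Y chromosome occurred together in every KO library, and RNA of female and male hearts in each KO library is a candidate explanation. It needs X-linked genes that escape inactivation to be higher in KO, and the median log2 fold change of 4 of them was 0.68, with Kdm5c at 0.97, Eif2s3x at 0.76, Ddx3x at 0.59 and Kdm6a at 0.00 (edgeR adjusted p = 0.978); after CMC it was 0.62, with Kdm6a at -0.21 (edgeR adjusted p = 0.0780), but of the 4 Y-linked genes Eif2s3y (-0.13, edgeR adjusted p = 0.227) did not pass, so the explanation stays open. Whether this makeup gives the calls between KO and WT as a whole was put to a test written before its result. The KO library with the most Xist was to lie at least 1.2 times as far from WT as the others over called autosomal genes. Each KO library lay between 0.975 and 1.01 times as far. Taking only called genes favours those with little spread among the KO libraries, which limits the test. In untreated KO, replicate 1 had 1.46 times the Xist of the others and the lowest sum of Y-linked genes, 200 per 1000000 nuclear counts against 236 and 242. It lay 0.984 times as far, which argues against sex makeup as the whole cause of the untreated calls. After CMC, replicate 1 had 1.23 times the Xist of the others, and its Y-linked sum of 223 lay close to the 229 and 233 of the others. Ddx3y and Kdm5d were lowest and Uty and Eif2s3y highest in it. The KO libraries after CMC thus differed too little in these genes for the test to decide there. A part of the calls that comes from sex makeup stays open in both treatments.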
